A study of Drosophila melanogaster with 3 samples.

How the data were processed

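H3K27me3 chromatin immunoprecipitation was done in S2 cells that carried an empty vector or FLAG-tagged human EZHIP in a copper-inducible plasmid. Per the labels' protocols, cells were selected with puromycin, induced with 5 or 10 µM copper sulfate for 72 h and fixed with 0.8% paraformaldehyde for 8 min. Chromatin was then digested with micrococcal nuclease, precipitated with a monoclonal H3K27me3 antibody and made into libraries with an NEBNext Ultra kit. The 3 samples form 3 groups of 1 library, named from the sample titles.

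The authors deposited 1 list of peaks per library, with 3 columns holding the chromosome, start and end coordinates of each peak, no header, and no score, signal, fold or p-value. The submitters' processing notes name Bowtie 1.0.0 and deepTools and the builds dm6 and mm9, without roles. The peak caller, its threshold, any input control and any scaling between libraries are not given in the sources used here. Peaks in all 3 lists start and end on a 200 bp grid, do not overlap, and lie at least 5201 bp apart, so nearby windows had been joined before deposit. Each end is 1 bp short of the grid, and lengths were computed from the positions as listed. X peaks and genes fit the Release 6 (dm6) coordinates of the gene table, so dm6 was used throughout. Depth per sample is unknown, and a library with fewer reads or weaker enrichment would yield fewer and shorter peaks.

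Positions are printed 1-based. Arm lengths were taken up to the last annotated gene or peak on 2L, 2R, 3L, 3R, 4 and X (133562553 bp in all). Gene positions came from an NCBI gene table of the same assembly, which gives spans but no strand, exons or sequence. All 196 genes of the 13 fixed lists (2 of them in 2 lists) were found, 4 through a synonym. The table held 13922 protein-coding genes on the arms. Overlaps, coverage and chance levels were computed with bedtools 2.31.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9. Analyses used each list as deposited unless stated.

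Control peaks were to be joined across gaps of at most 3 kb into domains. The kept share of a domain or gene is the share of its control-covered bases that were also covered in an EZHIP library. A gene's span is the gene with 1 kb at each end, and genes needed 500 bp of control coverage for a kept share. Chance levels came from 1000 random placements of the EZHIP peaks within their arms. Gene lists were compared with 10000 random lists of equal size drawn from protein-coding genes, matched on gene length (10 strata) for coverage and on control-covered bases (5 strata) for kept shares. Percentiles count ties at 50% weight. Alternatives were judged against Wilson intervals for shares of peaks, domains and genes, against bootstrap intervals over domains for edge differences, and for shares of bases against a nominal Wilson band that takes the number of control peaks as n. The coverage function gave the same shared bases as bedtools. On a simulated list in which known control peaks were removed or trimmed, the 1309 removed domains and the 41.0% of kept bases were recovered.

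The groups, comparisons, gene lists, most alternatives (the closing section names the later ones) and the rule for named genes were fixed before the data were examined. The rule named the 8 homeotic genes, the main genes of the 10 widest domains, of the 6 with the lowest and the 6 with the highest kept share at 10 µM among those of 10 kb and over, and of the 4 longest new intervals at 10 µM, and the members of each list with the most control coverage. The segmentation genes named other than inv, knrl and opa were chosen after their values were seen. So were Mef2, sna, byn, ase, ind, sv, ph-d and Psc. Also chosen then were the new intervals at 5 µM and the chance levels and independent losses by domain size. The new coverage by chromosome and the gene families in the closing section were chosen then too. Features around transcription start sites, exons and introns, and PHO and GAF motif densities, had been planned but need strand, exon or sequence data, so they were not analysed. No score was given to apply a stricter threshold.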

Results

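H3K27me3, the histone mark written by Polycomb repressive complex 2 (PRC2), was mapped by chromatin immunoprecipitation and sequencing in S2 cells, a Drosophila line with haemocyte-like features. The cells carried an empty vector or human EZHIP, a protein known to inhibit PRC2, under a copper-inducible promoter. There were 3 libraries with 1 library in each group: empty vector with 10 µM copper (the control), EZHIP with 10 µM copper and EZHIP with 5 µM copper, each after 72 h of induction. No empty-vector library at 5 µM copper was analysed here, so EZHIP at 5 µM differs from the control in copper as well. Each library was represented by a list of peak positions (dm6 coordinates) without heights, so the sequencing depth behind the peaks is unknown. With 1 library per group, no difference between groups could be set against a replicate spread, and no p-value is given. Intervals are Wilson 95% intervals over peaks or domains unless named otherwise, and cover counting error only.

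Far less of the genome was covered by H3K27me3 peaks in the cells with EZHIP. Peaks covered 52.0 Mb in the control, which is 38.9% of the chromosome arms. They covered 34.8 Mb (26.1%) with EZHIP at 5 µM copper and 14.2 Mb (10.6%) at 10 µM, 3.65-fold less than in the control. The number of peaks differed less, with 2600 in the control, 2281 at 5 µM and 1687 at 10 µM, because the peaks were also shorter. The median width was 8.80 kb in the control (quartiles 2.60 and 22.8 kb), 7.20 kb at 5 µM (2.60 and 17.6 kb) and 3.40 kb at 10 µM (0.799 and 8.20 kb). Over peaks of 1 kb and over, the medians were 10.2, 8.60 and 5.60 kb in the same order. Peaks of 50 kb or more numbered 273, 131 and 47. The longest peak was similar in all 3 libraries, at 294.0, 292.0 and 278.0 kb. The shortest was 599 bp in the control and at 5 µM but 399 bp at 10 µM. Whether the lists were called with the same settings is not known.

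**Figure D1:**
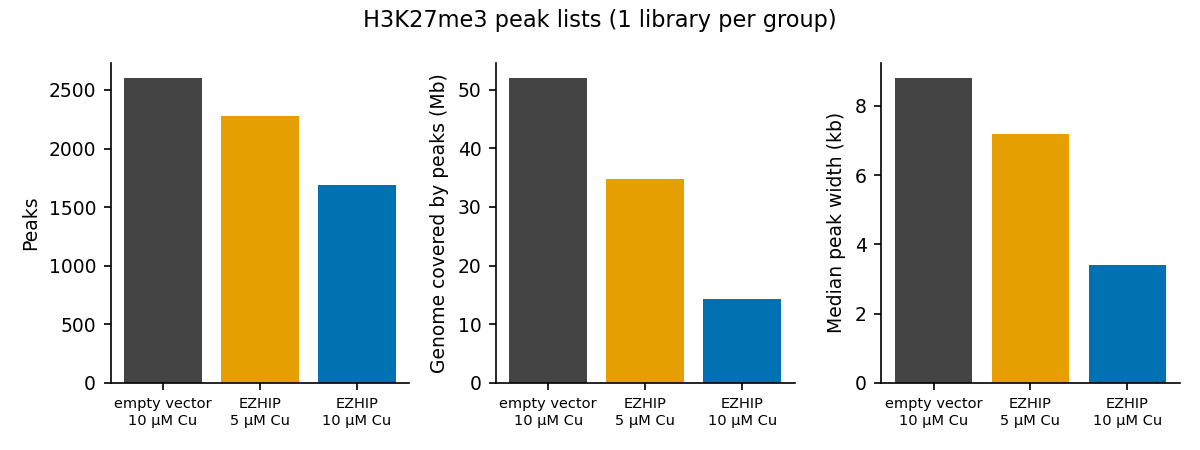
Number of H3K27me3 peaks, genome length covered by peaks (Mb) and median peak width (kb) in each library, 1 bar per library, no error bars because there was 1 library per group. Covered length goes from 52.0 Mb in the control to 34.8 Mb and 14.2 Mb with EZHIP at 5 and 10 µM copper.

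The first comparison, empty vector against EZHIP at 10 µM copper, asks where the mark remains when PRC2 is impeded. Of the control-covered bases, 27.3% were still covered in the EZHIP cells, and 960 of the 2600 control peaks (36.9%, interval 35.1 to 38.8%) still overlapped a peak by at least 1 bp. Placing the EZHIP peaks at random within their arms gave 11.8% of bases on average (highest of 1000 placements 13.3%) and 28.9% of peaks (highest 31.2%). What remained lay inside the control peaks. Of the 1687 EZHIP peaks, 1683 overlapped a control peak, and 99.6% of their bases were control-covered. Many control peaks were broken up, with 359 holding 2 or more separate EZHIP pieces and 601 holding 1. At 5 µM copper, 66.2% of control-covered bases and 1591 control peaks (61.2%, interval 59.3 to 63.0%) remained, against 28.9% of bases and 46.7% of peaks by random placement.

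Each control peak was treated as a domain, since no gap between peaks of a list was below 5201 bp and joining across 3 kb changed nothing. At 10 µM copper 1640 domains (63.1%) held no EZHIP peak and are called lost. A further 669 (25.7%) kept under 50% of their covered bases, and 291 (11.2%) kept 50% or more. At 5 µM the numbers were 1009 (38.8%), 516 (19.8%) and 1075 (41.3%). Among domains under 2 kb, 97.1% were lost at 10 µM and 88.9% at 5 µM. Among those of 30 kb and over, 15.5% were lost at 10 µM and 0.978% at 5 µM. A wide domain is less often missed under any placement: random placement lost 88.7% and 73.9% of the domains under 2 kb and 35.5% and 17.7% of those of 30 kb and over. The share of covered bases kept, which random placement left near 10% in every class at 10 µM (9.77% to 12.2% on average), was 1.66% in domains under 2 kb and 33.6% in those of 30 kb and over. At 5 µM these shares were 8.67% and 76.2%, against 23.9% and 29.9% by random placement. The random placements spread over whole arms, whereas the EZHIP peaks lay almost wholly inside control peaks. Random placement kept 11.8% and 28.9% of all control-covered bases at 10 and 5 µM, against 27.3% and 66.2% observed. It therefore gives no level for peaks that stay inside control peaks. Set against the observed shares of all control-covered bases, domains under 2 kb kept less and those of 30 kb and over kept more. Even so, the 511 domains of 30 kb and over kept a median of only 19.3% of their covered bases at 10 µM (quartiles 3.03 and 53.3%), against 81.2% at 5 µM. They held 66.3% of all control-covered bases and 81.7% of those kept at 10 µM.

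**Figure D2:**
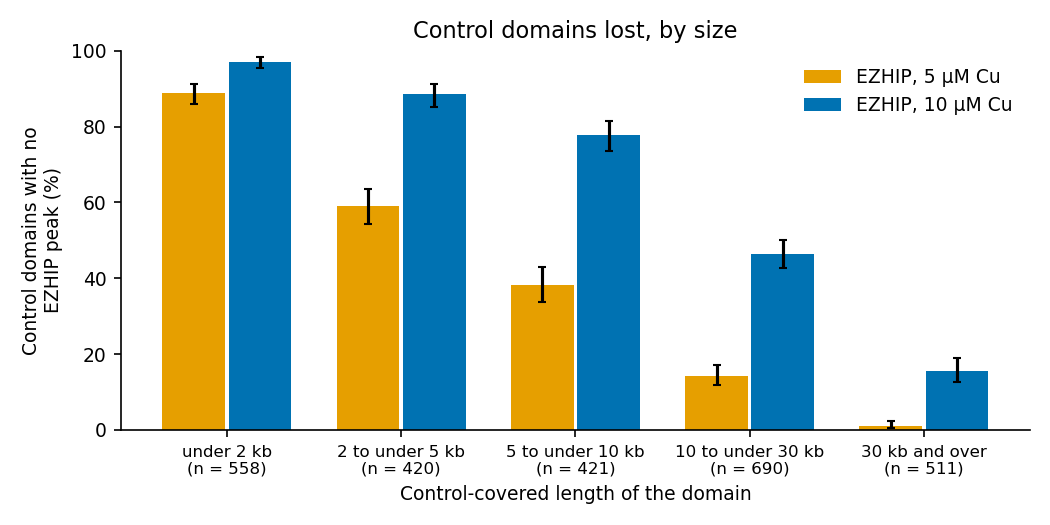
Share of control domains with no EZHIP peak (%, y axis) by control-covered length of the domain (x axis, with the number of domains), for EZHIP at 5 and 10 µM copper. Bars are 1 library each and error bars are Wilson 95% intervals over domains. The lost share goes from 97.1% under 2 kb to 15.5% at 30 kb and over for 10 µM copper.

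The widest control domains went opposite ways at 10 µM copper. Nearly whole at 99.1% was the domain holding Antp and Scr (3R: 6823801 to 7063999), and at 99.3% the one holding abd-A and Abd-B (3R: 16762601 to 16981799, 219.2 kb), whose main gene by covered length was MSAmiP. The domain at hth, a homeobox gene acting with the homeotic proteins, kept 99.4% of 279.6 kb (3R: 10416601 to 10696199). The widest of all, with CG4374 as its main gene (3R: 23361001 to 23654999), kept 91.6%. The domain at osp (2L: 14369801 to 14642599) kept 81.3%, and the one at the spalt-related gene salr (2L: 11284801 to 11507799) kept 77.2%. The other 4 of the 10 widest kept little: 10.5% at Elk, a potassium channel gene, 8.24% at cpo, an RNA-binding protein gene, 3.22% at side-V and 0.237% at klg, the last 2 being genes of cell-surface proteins. These 4 kept 87.8%, 62.3%, 57.3% and 53.9% at 5 µM.

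Of the 1201 domains with 10 kb or more of covered bases, 399 were lost and 61 kept 90% or more at 10 µM copper. The widest lost domain lay at side (CG31062, 3R: 27351801 to 27520999, 169.2 kb), which encodes an immunoglobulin-superfamily axon guidance protein. The next were at side-VIII (CG12484, 2R: 20378201 to 20543999), beat-IIa (CG14334, 3R: 17223001 to 17373199), CG34353, the RNA-binding protein gene Rbp6 and CG45263. At 5 µM these 6 kept between 31.6% and 61.8%. Of the 6 with the highest share, all at 100% in both EZHIP libraries, 5 lay at trh (3L: 367201 to 402599), Cph (X: 7191001 to 7222199), cad (2L: 20767801 to 20787199), ph-p (X: 2126601 to 2140199) and ey (4: 703001 to 716199), and 1 overlapped no protein-coding gene (X: 4588801 to 4602599). trh, cad and ey encode transcription factors of tracheal, posterior and eye development, and ph-p encodes a Polycomb protein.

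**Figure D3:**
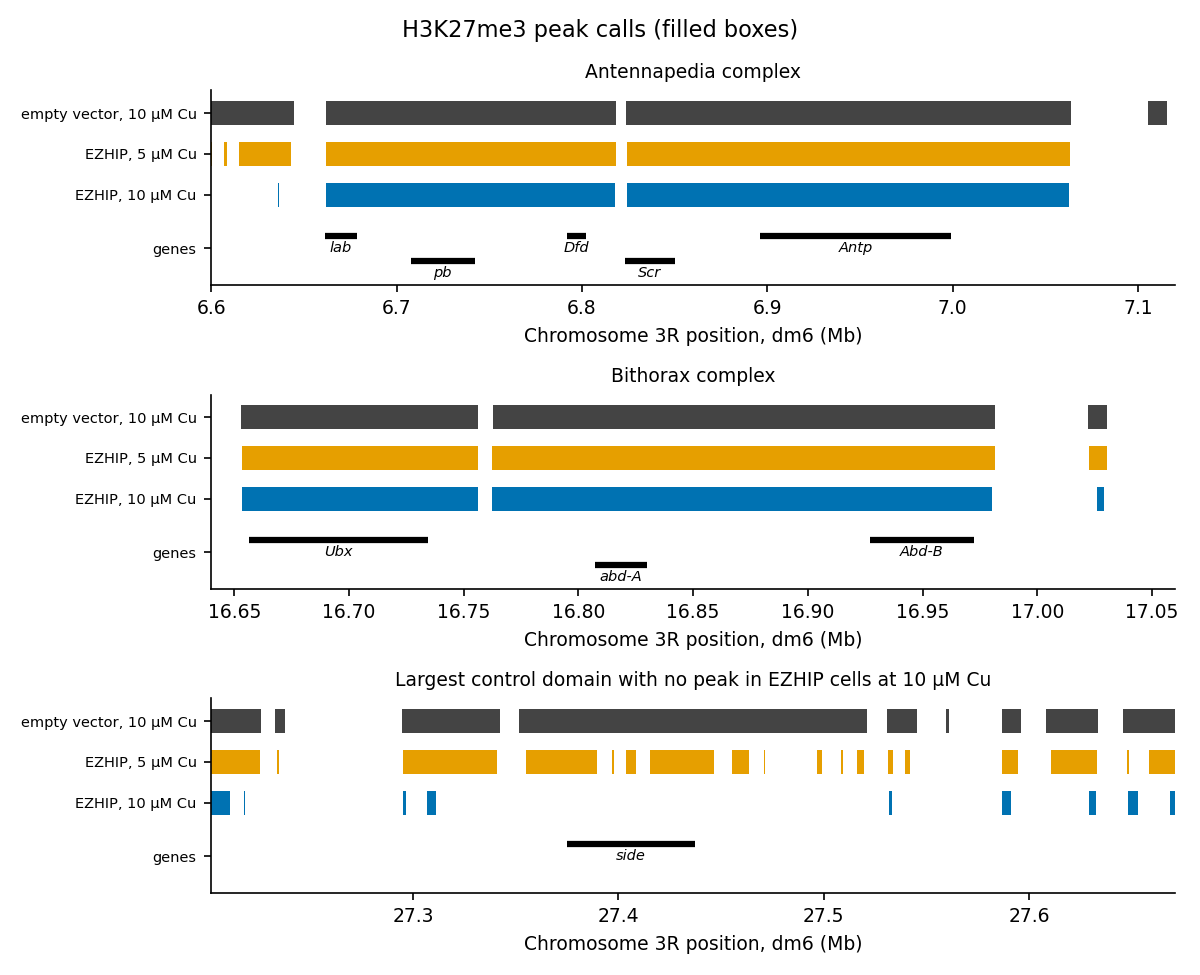
Peak calls (filled boxes) in the 3 libraries along chromosome 3R (x axis, Mb, dm6) at the Antennapedia complex, the Bithorax complex and the widest lost domain, with genes as black bars. Both homeotic complexes are covered almost alike in all libraries, whereas the 169.2 kb domain at side is broken up at 5 µM copper and has no peak at 10 µM.

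Homeotic genes and most genes of the segmentation and transcription factor lists kept their coverage. All 8 homeotic genes were covered over 50% or more of their span (the gene with 1 kb at each end) in the control and in both EZHIP libraries. At 10 µM, 7 of them, lab, pb, Dfd, Antp, Ubx, abd-A and Abd-B, kept 100% of their covered bases, and Scr kept 97.1%. Antp (CG1028, 3R: 6896253 to 6999228) had 105.0 kb of control-covered span and Ubx (CG10388, 3R: 16656623 to 16734426) had 79.8 kb. Of the 22 segmentation genes with at least 500 bp of control coverage, 18 kept 90% or more at 10 µM, among them inv (2R: 11474465 to 11509695), en, knrl, opa, eve and the ligand genes wg and hh. The other 4 kept less than 50%: tll 48.9%, hkb 27.5%, Kr 23.6% and gt 0%. Of 20 appendage and eye factors, 18 kept 50% or more, with nub at 100%, pdm2 at 95.8% and bi at 70.9%. Of 14 mesoderm and heart factors, 11 kept 50% or more, with lbl and H15 at 100% and twi at 81.5%. The other 3, Mef2, sna and byn, kept 0%. Of 21 neural and head factors, 17 kept 50% or more, with Lim1 at 76.6% and oc at 68.9%. The others were Lim3 at 31.6%, sv at 2.12%, and ase and ind at 0%.

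Across all 5845 protein-coding genes with 500 bp or more of control coverage, the median kept share at 10 µM was 0%, 61.5% kept nothing and 21.2% kept 50% or more. Genes covered over 50% or more of their span numbered 4570 in the control, 2976 at 5 µM and 1110 at 10 µM, of 13922. The median kept share was 100% for the homeotic, segmentation, appendage and eye, and mesoderm and heart lists, and 97.8% for the neural and head list. Among 10000 random gene lists of equal size and matched control coverage, the homeotic median was at percentile 99.995 and the other 4 at percentile 100. The typical medians of the random lists, in the order given, were 12.1, 2.02, 10.5, 5.32 and 5.36%. This places the lists within these libraries only. Neighbouring genes share domains and are not independent.

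Signalling ligand genes were split. Of 15 with control coverage, 6 kept 50% or more at 10 µM, 3 kept less and 6 kept nothing, with a median of 38.4% (percentile 94.3 among random lists, whose typical median was 9.30%). wg and hh, which are also in the segmentation list, kept 100% and 98.6%. The epidermal growth factor-like ligand gene vn kept 46.8%, the fibroblast growth factor gene ths 12.3%, and the bone morphogenetic protein gene dpp 0%. At 5 µM ths kept 81.4% and dpp 24.3%.

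Control coverage of the lists of differentiated cell types is given by list, and differences between the lists were not tested. Of 8 muscle genes 6 were covered over 50% or more of their span in the control, of 10 germline and gonad genes 4, of 13 haemocyte genes 4 and of 8 neuron genes 2, against 32.8% of all protein-coding genes. The control percentiles of the list medians were 99.3, 87.5, 34.0 and 60.7 in that order. At 10 µM the numbers were 0, 0, 0 and 1. Among 6 muscle genes with control coverage, none kept 50% or more: Mhc, the muscle myosin heavy chain gene, kept 19.0%, Mlp60A 43.8% and Mlc2 0%, against 79.2%, 87.0% and 65.7% at 5 µM. Of 6 haemocyte genes with control coverage, 5 kept nothing, including Hml and NimC1, and Col4a1 kept 26.4%. Of 7 germline and gonad genes, 6 kept nothing, including vas and osk, and tj kept 29.1%. Of 6 neuron genes, 4 kept nothing, including Syt1, while brp kept 77.6% and Rdl 53.7%. The median kept share at 10 µM was 0% in the muscle, haemocyte, germline and neuron lists, with percentiles of 18.7, 17.0, 45.6 and 13.2 in that order, where the random lists themselves had typical medians of 5.41, 5.76, 0 and 6.80%.

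Polycomb group genes were largely outside the mark. Of 20, 2 were covered over 50% or more of their span in the control, jing (2R: 6502006 to 6621792) and ph-p. The span of jing was covered over 86.0% in the control and 64.5% at 10 µM, ph-p kept 100%, and Su(z)2 kept 0% of its 3.00 kb. At 5 µM, 4 of the 20 were covered over 50% or more: jing, ph-p, Psc and Su(z)2. The span of Su(z)2 was covered over 22.4% in the control, 60.4% at 5 µM and 0.738% at 10 µM, and that of Psc over 0, 62.4 and 0%. The median kept share over these 3, that of jing, was at percentile 93.1. ph-d, a close copy of ph-p, had no coverage in any library, whereas the span of ph-p was covered over 90.2% in each. How reads that match both copies were assigned is not known. None of the 9 trithorax group genes and none of the 18 housekeeping genes was covered over 50% of its span in any library. In each of these lists 1 gene had 500 bp of control coverage, trx (0.642 kb) and Act5C (0.599 kb), and neither kept any at 5 or 10 µM. ash1 and ash2 had none, and Hsc70-4 and RpS3 had 0.214 and 0.207 kb.

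**Figure D4:**
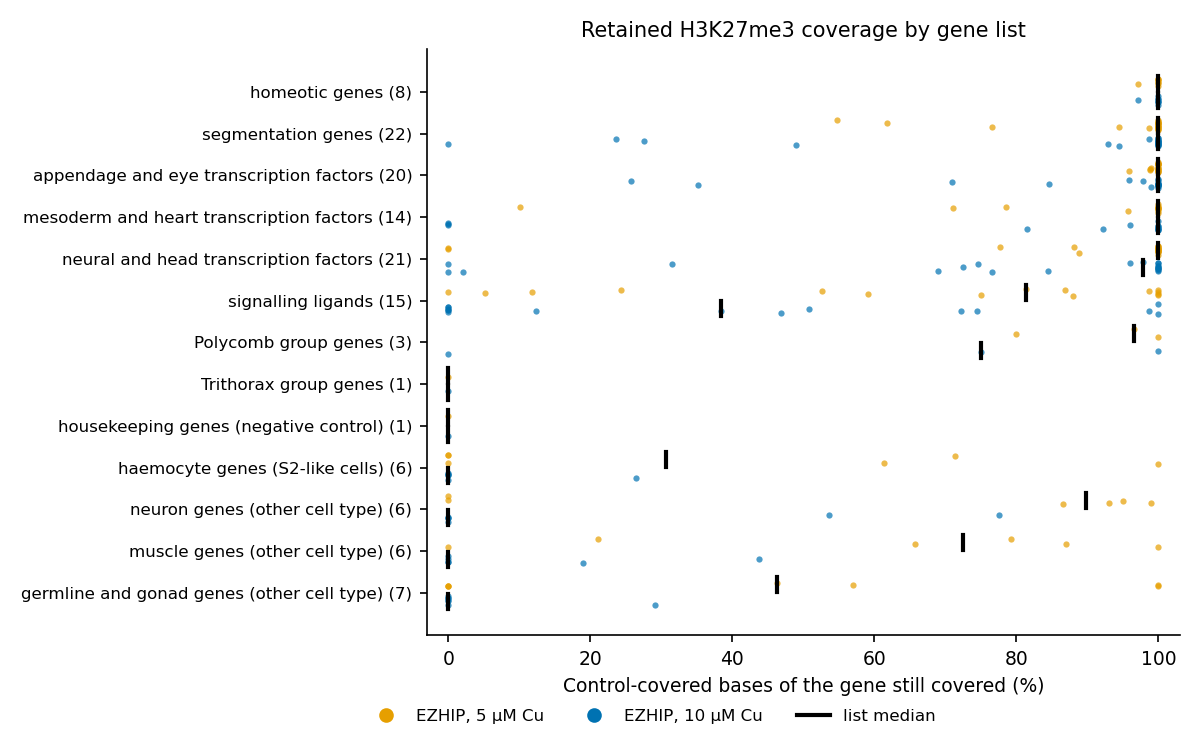
Share of control-covered bases still covered (%, x axis) for each gene of the 13 lists (y axis, with the number of genes that had at least 500 bp of control coverage), at 5 and 10 µM copper, 1 point per gene and a black bar at the list median. At 10 µM copper the medians of the transcription factor lists sit at or near 100%, although some of their genes lie at 0%. The muscle, haemocyte, germline and neuron medians are at 0%.

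The second comparison, EZHIP at 5 µM against 10 µM copper, asks how coverage differs between the copper doses that induce EZHIP. Coverage at 10 µM was almost nested in that at 5 µM. Of the bases covered at 10 µM, 99.5% were covered at 5 µM, and of those covered at 5 µM, 40.7% were covered at 10 µM. Of the control-covered bases without a peak at 5 µM (17.6 Mb), 99.7% also lacked one at 10 µM, where 72.7% would be shared by independent losses at 1 rate for all domains. Of the 1009 domains lost at 5 µM, 1003 were lost at 10 µM, against 636.4 for independent losses at 1 rate for all domains and 873.2 for independent losses within each of the 5 size classes. Both comparisons use the same control list, so part of this overlap may come from the control. The kept share was lower at 10 µM than at 5 µM in 1563 domains, equal in 1028 and higher in 9. Of the 1075 domains that kept 50% or more at 5 µM, 263 were lost at 10 µM.

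Within domains of 10 kb and over, the central part kept more than the ends. At 10 µM the central 50% of these domains kept 31.8% of its covered bases and the outer 25% at each end 27.4%, a difference of 4.41 percentage points. At 5 µM the values were 74.5% and 66.4%, a difference of 8.03 points. The interior share was the higher in 485 of 796 partly kept domains at 10 µM and in 763 of 1051 at 5 µM. The kept pieces of each partly kept domain were also slid to a random place inside it, as a block with fixed spacing. This gave 489.6 and 761.7 domains on average, and differences of up to 3.52 and 3.72 points in 1000 slides. The count of domains thus did not exceed the slides, in which a wide block could move little. The base-weighted differences of 8.03 points at 5 µM and 4.41 points at 10 µM both lay above the highest slide. The bootstrap interval over domains at 5 µM, 6.66 to 9.55 points, also lay above the slides. That at 10 µM, 2.97 to 5.94, reached into them. With the outer 10% at each end as the edge, the differences were 7.83 and 14.4 points, and with domains joined across 10 kb they were 3.29 and 6.47, settings for which no slides were run.

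Coverage was lower with EZHIP on every arm analysed. At 10 µM the kept share of control-covered bases was 25.5% on 2L, 27.8% on 2R, 24.5% on 3L, 30.3% on 3R, 24.8% on X and 37.5% on the small chromosome 4, which had 13 control peaks. At 5 µM it was 58.9, 71.2, 62.6, 72.3, 57.3 and 58.4% in the same order. Coverage of the X was low from the start, at 15.1% of the arm in the control against 37.0 to 50.2% of the large autosomal arms.

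New coverage in EZHIP cells was a small share of the whole, and a larger share on the small chromosome 4, where little was covered. At 10 µM, 4 peaks lay wholly outside control peaks, and 64.0 kb, or 0.450% of covered bases, was not control-covered. At 5 µM these were 14 peaks and 408.6 kb, or 1.17%. On chromosome 4, 27.4% of the covered bases at 10 µM and 32.3% at 5 µM were not control-covered, and on X 4.14% and 6.68%. The span of the eye gene ey on chromosome 4 was covered over 51.8% in the control, 85.5% at 5 µM and 84.0% at 10 µM. The longest new intervals at 10 µM were 6.80 kb in the zinc-finger homeobox gene zfh2 (4: 503401 to 510199), 6.60 kb at bi (X: 4409000 to 4415600), 6.60 kb outside protein-coding genes (X: 9305200 to 9311799) and 6.20 kb at CG33798 (2R: 12989401 to 12995599). Those at 5 µM were 13.8 kb in zfh2 (4: 517201 to 530999), 13.4 kb (X: 9714201 to 9727600) and 10.6 kb (X: 4602600 to 4613200) outside protein-coding genes, and 10.6 kb at Psc (2R: 12967001 to 12977599).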

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

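Joining peaks across 10 kb in the library descriptions, filling gaps of 10 kb and gene spans without added sequence were chosen after seeing the data, and the other alternatives before. Joining or filling across 1 or 3 kb (45 recomputed values) tested nothing, because no gap was that short. Of the other 93, 76 stayed within their interval or, for counts and widths, within 1.5 times the main value, and 17 did not. Of the 76, 35 were gene spans without added sequence, judged against the wide intervals of short gene lists. A reversal was looked for only in the edge differences, and none was seen. The share of control peaks overlapped at 10 µM copper was 11.2% when 50% of the control peak had to be covered, which is stricter by construction, 31.2% with peaks of 1 kb and over, and 53.8% with equal lists of the 1687 widest peaks, which drop narrow control peaks. At 5 µM it was 41.3% for 50% of the peak and 71.1% for equal lists. Filling gaps of 10 kb gave 29.4% and 68.2% of bases kept at 10 and 5 µM. Joining across 10 kb gave 57.9% and 35.6% of domains lost at 10 and 5 µM, edge differences of 3.29 and 6.47 points, 1668 control peaks of median width 13.8 kb and 1492 peaks of 11.3 kb at 5 µM. Peaks of 1 kb and over had a median width of 5.60 kb at 10 µM. With the outer 10% as the edge, interior exceeded edge by 7.83 points at 10 µM and 14.4 at 5 µM. Apart from the settings noted as stricter or dropping peaks, the cause was not tested. No paired analysis was possible because each group has 1 library. Stricter scores, start-site windows and a longer PHO motif were not run. Unknown depth limits every comparison of covered length.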

Other observations

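The tests on gene families, kept domains and domain edges were chosen after the results were seen, and the test on new bases was fixed before. Many genes of sensory and cuticle families were covered in the control. Of 59 odorant receptor genes, 42 were covered over 50% or more of their span in the control, 28 at 5 µM copper and 6 at 10 µM. The corresponding numbers were 44, 18 and 3 of 60 gustatory receptor genes, 42, 28 and 12 of 60 ionotropic receptor genes, 35, 18 and 6 of 51 odorant-binding protein genes, 23, 15 and 3 of 29 pickpocket channel genes, 55, 45 and 13 of 70 Cpr cuticle protein genes, and 22, 14 and 4 of 23 Osiris genes. Over all protein-coding genes the shares were 32.8, 21.4 and 7.97%. At 10 µM the median kept share was 0% in each of these 7 families, at percentiles between 36.9 and 49.7 among matched random lists, whose typical medians were also 0%. Of 88 cytosolic ribosomal protein genes, 6 were so covered in the control, and of 73 mitochondrial ones 0.

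At 5 µM copper, the median kept share was 0% over 51 cytochrome P450 genes with control coverage (percentile 0.005 among matched random lists, whose typical median was 74.2%), 22.3% over 48 gustatory receptor genes (percentile 2.43) and 31.4% over 40 odorant-binding protein genes (percentile 3.07). It was 100% over 45 odorant receptor genes (percentile 90.4), 56 Cpr genes (95.6), 22 Tweedle genes (95.7) and 27 UDP-glycosyltransferase genes (91.5), 94.8% over 15 dpr genes (91.4) and 92.2% over 21 seminal fluid protein genes (89.9). These medians hide splits within families. Genes that kept nothing and that kept 50% or more numbered 26 and 21 (P450), 16 and 18 (gustatory receptor) and 17 and 19 (odorant-binding protein). They numbered 15 and 28 (odorant receptor), 5 and 47 (Cpr), 1 and 21 (Tweedle) and 6 and 19 (UDP-glycosyltransferase). Across all 5845 genes with control coverage, 27.7% kept nothing and 58.5% kept 50% or more. Ionotropic receptor genes (78.3%, percentile 47.9), Osiris genes (71.6%, percentile 46.4) and pickpocket genes (67.9%, percentile 28.1) lay nearer the middle of the random lists. Cytosolic and mitochondrial ribosomal protein genes had 9 and 3 members with control coverage, with medians of 14.8% and 0%. The beat and side families, with 43.0% over 14 genes and 33.5% over 7, were looked at because members head the widest lost domains, so their place among random lists says nothing further. Differences between families were not tested. At 10 µM, Tweedle cuticle genes kept a median of 15.1% (22 genes, percentile 99.5) and dpr adhesion genes 22.6% (15 genes, percentile 80.2), and the other 14 families had medians of 0%. Members of a family often sit in clusters, so they are not independent.

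Domains of 10 kb and over that held a transcription factor gene of the fixed lists kept a median of 80.8% of their covered bases at 10 µM copper (58 domains, quartiles 59.4 and 97.8%, 3 lost). Domain size alone was argued against: 1000 draws from the 1143 other domains, matched on covered length, had medians between 1.86 and 24.3%. A lower depth or enrichment of the EZHIP library against a fixed calling threshold cannot be told apart from a real loss, because 99.6% of the EZHIP bases lay inside control peaks, which either would give, and no signal values were at hand to rank kept and lost domains. A biological hypothesis, that these domains hold the strongest sites of PRC2 recruitment and that EZHIP mainly limits methylation away from such sites, was not tested: maps of PRC2 binding or of signal height, not used here, would be needed.

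The base-weighted excess of interior over edge retention at 5 µM, 8.03 points (bootstrap interval 6.66 to 9.55), was above the highest of 1000 random slides (3.72), which argues against chance placement over the covered bases as a whole. At 10 µM the excess of 4.41 points was also above the highest slide (3.52), but its bootstrap interval (2.97 to 5.94) reached below that slide. The evidence against chance placement is therefore weaker at 10 µM and does not settle it. The number of domains with the higher interior share, 485 at 10 µM and 763 at 5 µM, lay within the slides (456 to 524 and 733 to 787), so chance placement may account for the count. This is a limited test, because the pieces slide as a block and a wide block can move little. Weaker signal at domain ends falling below a calling threshold was not tested and stays open beside reduced spreading.

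For bases covered in EZHIP cells outside control peaks, a gap in the control calls stays open where the piece touches a control peak. Of these bases, 78.4% at 10 µM and 89.1% at 5 µM lay in pieces touching a control peak, but this decides nothing, because each piece of an EZHIP peak that overlaps a control peak must border it (24 of 28 pieces at 10 µM and 172 of 186 at 5 µM). Pieces bridging 2 control peaks held 18.4% and 29.2% of these bases. Near the Polycomb genes Psc and Su(z)2, new coverage at 5 µM included 10.6 kb at Psc (2R: 12967001 to 12977599), and at 10 µM 6.20 kb at CG33798 (2R: 12989401 to 12995599).

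A peak was called on the mitochondrial genome in every library, 13.999 kb in the control, 11.4 kb at 5 µM and 9.60 kb at 10 µM. This peak is counted in the peak numbers, domains and covered lengths above. Its length fell in the same order as the covered length of the libraries. Whether a difference in depth, enrichment or calling between the libraries lies behind that was not tested. On the Y chromosome 0 peaks were listed.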
